A study of Mus musculus with 3 samples.

How the data were processed

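RNA of mouse dorsal dermal fibroblast progenitors at embryonic day 12.5 was measured on Illumina MouseRef-8 bead arrays. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I treatment and checked on a Bioanalyzer, and biotin-labelled cRNA was made with an Ambion MessageAmp kit. Per the series' design text, cells were obtained by laser capture from 5 embryos and their RNA was pooled before amplification, and the 3 arrays were technical replicates. The number of independent RNA pools was therefore 1, and the 3 arrays, counted as n = 3 for the spread between arrays, limit the precision to technical error. Whether the arrays shared 1 labelling reaction was not given in the sources used here, so each SD covers hybridisation and possibly labelling. The scanner software, its version and the name of the normalization method were not given in the sources used here.

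The authors deposited a table of non-normalized bead intensity and a table of normalized intensity, as the values and the column names show, with 25697 probes for each array. Every normalized intensity in the deposited table equalled 1 slope times the non-normalized intensity plus 1 offset per array, with residuals of at most 0.0152. The slopes were 0.672, 2.07 and 0.699 for arrays 1, 2 and 3, and the offsets -57.2, -152 and -63.5. Values below 0 occurred at 6918, 6172 and 7122 probes. The authors' series value table held the same numbers, on a linear scale, with medians of 14.9, 21.5 and 15 and no centring. Per the file headers, each probe and array also had a detection p-value, equal in both deposited tables. These p-values came in steps of 1/798, as ranks against 798 negative control bead types would give, and the control signals themselves were not analysed here.

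A probe was called detected at a detection p under 0.01 on all 3 arrays. A gene was called detected if at least 1 of its probes was, and was valued by its probe with the highest mean normalized signal. No level of 1 probe was set against that of another. File symbols were updated through the RefSeq gene table of assembly GRCm38.p6. By symbol 17548 probes matched, by the name in the file's definition 1320 and by a synonym of 1 gene 5855, while 974 probes kept the file's name. Date-like symbols stood at 21 probes and were left as given. After the update 18120 file symbols became 17849 genes. A list member with no probe under its name or older name was not analysed here.

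Before the data were examined, 32 gene lists and 28 gene families defined by symbol patterns were fixed. They cover the dermal lineage, matrix and Wnt signalling, other cell types of the region, unrelated tissues, cell states and signalling pathways. For each list the number of measured genes detected was set against 10000 random lists of the same size drawn from all genes on the array, giving the range from percentile 2.5 to 97.5. These ranges describe the arrays, and no p-value across genes was made. The genes named in the text follow a rule fixed at the same time. It takes, in list order, the first 4 detected and the first 4 undetected members of each list, the first 8 in the dermal lineage, matrix and Wnt lists, and all members where 5 or fewer lie on a side. En1, Sox2, Twist2 and Xist were always included, as were all Hox, Wnt and Frizzled genes, the first 4 per side of other families in alphanumeric order, and the 10 genes with the largest SD of log2 signal. The rule gave 479 genes, some of which are not reported here.

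Reproducibility was measured as the SD of log2 normalized signal per probe detected on all 3 arrays, with Pearson's r and the median absolute log2 difference for each pair of arrays. Differences between arrays by brightness were medians over probes in ranges of non-normalized signal on array 1, with standard errors from 500 bootstrap samples. Intervals for the noise of array 2 came from 100 bootstrap samples of probes, and those for pairs of probes from 1000 bootstrap samples of genes. For genes with several probes, the share in which all probes had the same state was counted. With 1 group, no comparison between groups and no fitted model was possible.

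The procedures were tested on simulated data. Of 200 random lists of 28 genes drawn from the 17849 genes, 3.5% fell outside the central range, and of 200 lists with 80% of members planted as detected, 98% lay above it. A simulated SD of 0.1 on 9693 probes was recovered as 0.0999 by the root mean square of the SDs per probe. The results report the median and an upper percentile of those SDs instead. Whether the median or that percentile recovers a set SD was not tested. For the noise of array 2, simulated on 6970 probes, a ratio of 1 was recovered as 0.988 and a ratio of 2 as 1.91.

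Alternatives covered detection p thresholds of 0.05 and 0.001, detection on at least 2 or at least 1 array, a requirement that every probe of a gene be detected, and a signal threshold from chemosensory and beta-defensin probes. Each array was left out in turn, and random lists were matched on probes per gene. For reproducibility they covered no normalization between arrays, quantile normalization, the neqc method of limma with control signals inferred from the detection p, the series value table, all probes with a floor of 24, and a detection p under 0.05. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1. Number of value columns left unused was 0.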

Results

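Transcripts of the mesenchymal cells that give rise to the fibroblasts of back skin were measured in the mouse at embryonic day 12.5. These dorsal dermal fibroblast progenitors were cut from 5 embryos by laser capture, and the RNA was pooled before it was amplified and labelled. The embryos carried Cre recombinase at Engrailed1, a gene active in the part of the somite from which dorsal dermis arises, together with a Cre reporter at the Rosa26 locus. The 3 bead arrays, numbered 1 to 3, were technical replicates of 1 RNA pool, so each SD below describes the spread between arrays and not between embryos. The series held 1 group and gave no contrast between conditions. The question that remained was which transcripts the pool held above array background.

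A probe was called detected when its detection p lay under 0.01 on all 3 arrays, and a gene when at least 1 of its probes was detected. Each array read 25697 probes for 17849 genes. Array 1 detected 11542 probes (44.9%), array 2 detected 10022 (39.0%) and array 3 detected 10692 (41.6%). Of all genes, 7784 (43.6%) were detected on all 3 arrays. Signals are given as mean normalized signal ± SD in arbitrary units (n = 3 arrays), and a gene is valued by its brightest probe. Counts for each gene list are set beside the central 95% of 10000 random lists of equal size, which describes these arrays and is not a test. The genes drawn from include 1297 chemosensory and beta-defensin genes, of which 3 were detected, and this lowers the random ranges. A gene that was not detected was not shown to be absent, since 24 of 231 ribosomal, proteasome, respiratory chain and reference genes, most of which nearly every cell uses, were not detected either.

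The dermal fibroblast lineage list was detected at 23 of its 28 measured genes, where random lists gave 7 to 17. Both Twist genes, basic helix-loop-helix factors of early mesenchyme, were read clearly, with Twist2 at 2827 ± 181 and Twist1 at 2723 ± 146 (SD, n = 3). Pdgfra, the receptor that marks embryonic dermal mesenchyme, lay at 4106 ± 158. The homeobox gene Prrx1 lay at 1107 ± 50.2, Msx1 at 825 ± 10.6 and the retinoic acid binding protein gene Crabp1 at 1467 ± 83.6. Lef1 (66.4 ± 16.6) was detected close to background, by 1 of 2 probes. En1, whose locus drove the Cre line, was likewise detected near background at 46.6 ± 7.46, and its call was lost at a detection p under 0.001. The 5 genes not detected were Tbx15 (14.3 ± 29.4), Alx4 (18.6 ± 7.91), Msx2 (41.7 ± 10.9), Dkk2 (-4.32 ± 7.87) and Ebf1 (32.4 ± 11.1). Msx2 passed the threshold on 2 arrays, and Tbx15 and Ebf1 each on 1.

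**Figure D1:**
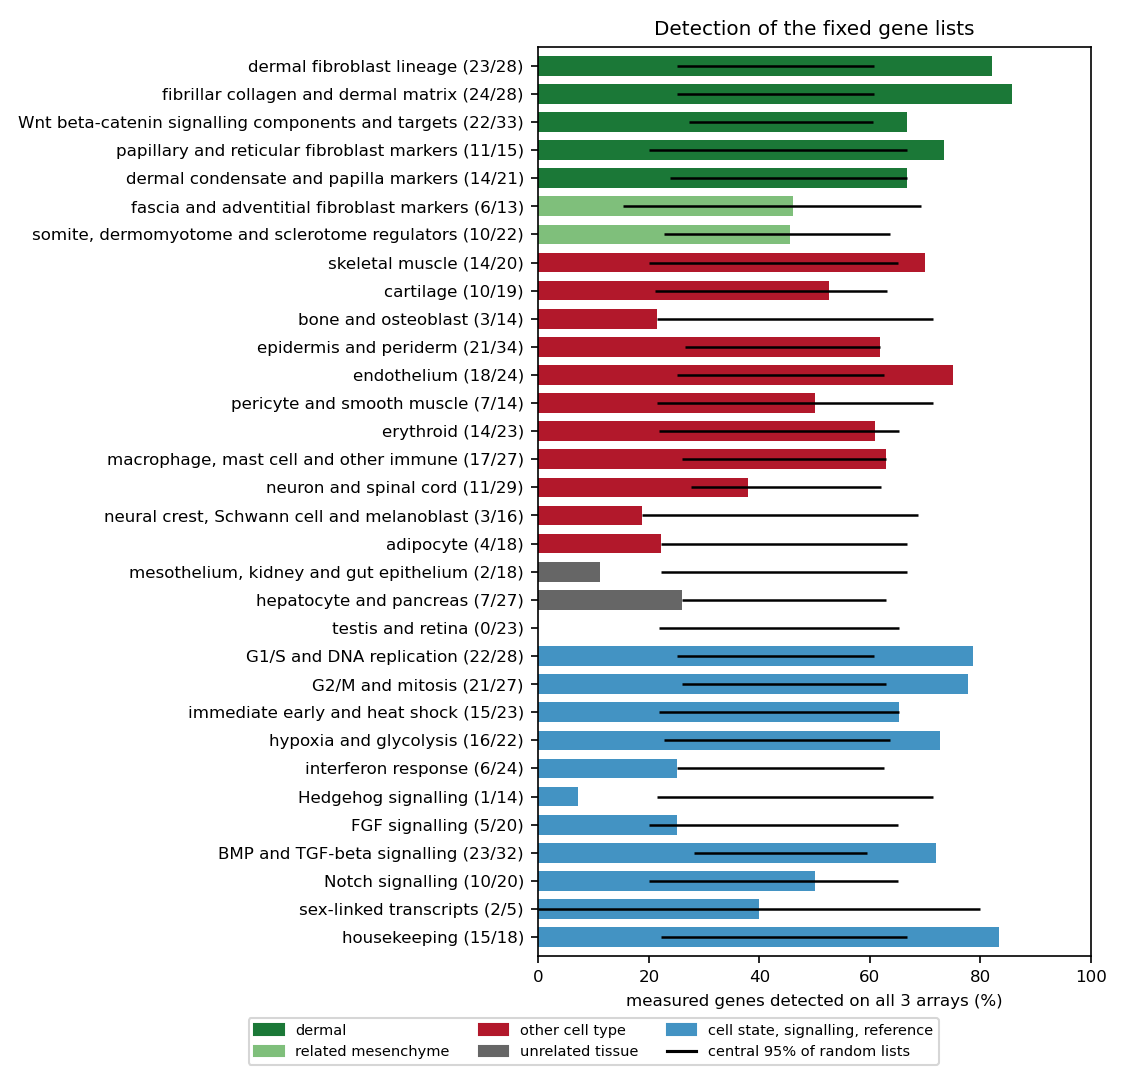
Horizontal bars give the percentage of measured genes of each list that were detected on all 3 arrays, with detected and measured counts in parentheses, and black lines span the central 95% of random lists of equal size. The dermal lineage (23 of 28) and dermal matrix (24 of 28) bars extend past their random ranges, as do others such as skeletal muscle (14 of 20) and endothelium (18 of 24), and the testis and retina list has no bar (0 of 23).

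Genes of the dermal extracellular matrix were detected at 24 of 28, above the 7 to 17 of random lists. The fibrillar collagen genes Col1a1 (209 ± 14.2), Col1a2 (221 ± 18), Col3a1 (4563 ± 202), Col5a1 (3164 ± 188) and Col5a2 (584 ± 46.2) were all detected, Col3a1 by 1 of 2 probes. Col6a1 (2680 ± 158), Col6a2 (249 ± 8.11) and Col12a1 (434 ± 39.2), which encode microfibrillar or fibril-associated collagens, were detected as well. The 4 genes not detected were Dpt, which encodes dermatopontin, at 2.13 ± 3.02, the matricellular gene Postn at 12.4 ± 6.24, Fbln5 at -0.599 ± 12 and Mfap5 at -0.691 ± 8.41. Across the whole collagen family 22 of 38 genes were detected (random lists 11 to 23). Laminin genes were detected at 4 of 9 (random lists 1 to 7), with Lama1 (257 ± 8.96), Lamb1 (165 ± 45.9), Lamb2 (357 ± 42.6) and Lamc1 (198 ± 36.6). Among matrix metalloproteinases 9 of 22 were detected (random lists 5 to 14), including the gelatinase gene Mmp2 at 5836 ± 145 and Mmp11 at 886 ± 19. ADAMTS proteases were detected at 7 of 15 (random lists 3 to 10), with Adamts2, whose product trims procollagen, at 244 ± 24.2. Integrins were detected at 8 of 19 (random lists 4 to 12), among them Itga6 at 185 ± 20. The integrin count fell to 5 when every probe of a gene had to be detected.

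Wnt/beta-catenin components and targets were detected at 22 of 33, where random lists gave 9 to 20. The feedback inhibitor Axin2, a direct target of the pathway, lay at 2244 ± 19.3, the Wnt inhibitor gene Apcdd1 at 3093 ± 114 and Nkd2 at 900 ± 81. Ctnnb1, which encodes beta-catenin, lay at 8621 ± 2264, its array values being 7139, 11228 and 7498. The transcription factor genes Tcf7 (139 ± 29.4) and Tcf7l2 (297 ± 26.2) and the secreted antagonist gene Dkk1 (208 ± 33.6) were detected. Members not detected included Nkd1 (18.2 ± 11.8), Sfrp4 (-6.35 ± 6.22), Frzb (23.8 ± 6.32), Rspo2 (-4.57 ± 5.07), Rspo4 (8.67 ± 3.17), Lgr6 (-0.625 ± 7.47) and the co-receptor gene Lrp5 (8.85 ± 8.07). Of the Wnt ligands 8 of 19 were detected (random lists 4 to 12): Wnt2 (517 ± 23.2), Wnt3a (61.1 ± 3.46), Wnt4 (392 ± 38.3), Wnt5a (2427 ± 52.7), Wnt6 (122 ± 18.8), Wnt7a (265 ± 26.5), Wnt7b (379 ± 11.6) and Wnt11 (50.2 ± 7.44). Wnt4 and Wnt6 are also members of the epidermis and periderm list. Wnt10b (-9.77 ± 18.9), Wnt1 (-8.13 ± 2.69) and Wnt16 (5.18 ± 9.91) were not detected. Neither were Wnt5b (64.5 ± 19.8) and Wnt10a (59.4 ± 17.8), which passed on 2 arrays each. The ligand count ran from 6 to 12 under the alternatives. Frizzled receptor genes were detected at 7 of 9 (random lists 1 to 7), including Fzd1 (626 ± 14.2), Fzd2 (1607 ± 129), Fzd7 (688 ± 77.4) and Fzd10 (2278 ± 270), while Fzd4 (24.8 ± 24.2) and Fzd8 (20.5 ± 11.1) were not.

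**Figure D2:**
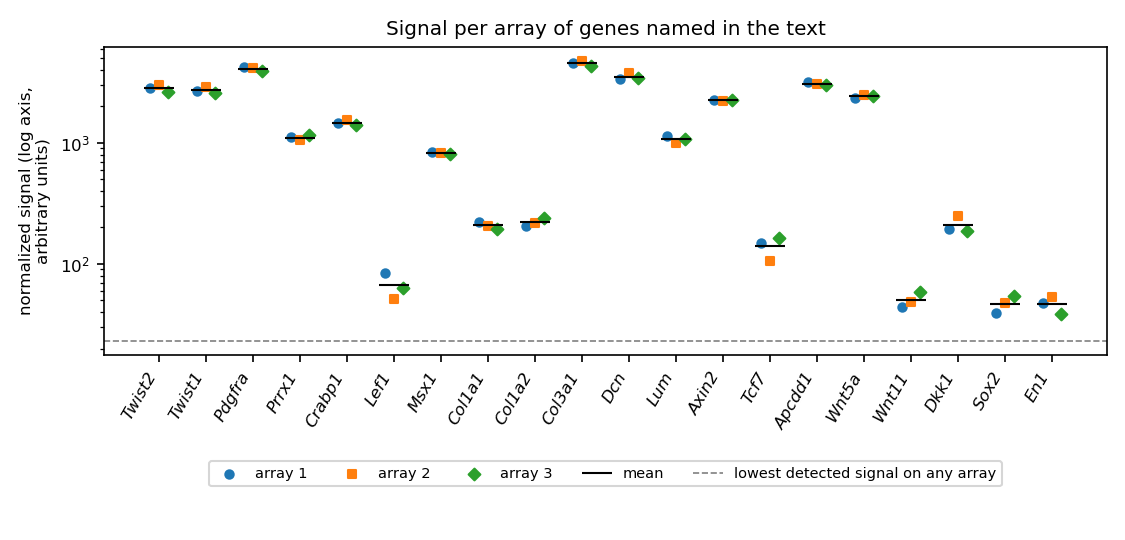
Normalized signal on a logarithmic axis in arbitrary units for dermal lineage, matrix, Wnt and condensate genes, with 1 symbol for each of the 3 arrays, a bar for the mean, and a dashed line at the lowest detected signal on any array (23.1). That line is the value of array 1, while the lowest detected signal was 44.3 on array 2 and 31.2 on array 3. En1, Sox2, Wnt11 and Lef1 lie closest to the line, and the arrays nearly coincide for Axin2 (2244 ± 19.3).

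Other signalling pathways differed in how many of their genes were read. BMP and TGF-beta genes were detected at 23 of 32 (random lists 9 to 19), with the ligand Bmp4 at 3080 ± 87.9, Bmp7 at 171 ± 2.83 and the receptor Bmpr1a at 1107 ± 103. Bmp2 (-2.65 ± 6.54), Bmp5 (17.2 ± 3.57), Bmp6 (16 ± 12.9) and Bmpr2 (22.6 ± 5.00) were not detected. Hedgehog genes gave 1 of 14, below the 3 to 10 of random lists. Smo, the pathway's transducer, lay at 589 ± 8.64 by 1 of 3 probes, while the target genes Ptch1 (17.4 ± 6.33) and Hhip (17.3 ± 0.962), and Gli3 (4.53 ± 3.53), were not detected. FGF genes gave 5 of 20 (random lists 4 to 13), namely Fgfr2 (54.9 ± 9.71), Fgf10 (136 ± 11.4) and the targets Dusp6 (2760 ± 369), Etv4 (201 ± 1.90) and Etv5 (58.4 ± 4.09), but not Fgfr1 (24 ± 4.89). Notch genes gave 10 of 20 (random lists 4 to 13), with Notch1 at 481 ± 14.3, Notch3 at 397 ± 19.5, Notch4 at 723 ± 45.6 and Jag1 at 268 ± 33.7. The insulin-like growth factor system gave 12 of 14 (random lists 3 to 10), with Igf2, a growth factor of the embryo, at 46223 ± 13934 and its mRNA-binding protein gene Igf2bp1 at 972 ± 6.88. Igfbp1 (-2.47 ± 4.05) and Igfbp6 (-0.0844 ± 8.74) were not detected. Eph receptors and ephrins gave 11 of 22 (random lists 5 to 14), with Efna5 at 2745 ± 17.7, and semaphorins and plexins gave 10 of 27 (random lists 7 to 17), with Sema3f at 1650 ± 61.4 and Sema3a at 490 ± 33. With every probe of a gene required, the counts were 15 for BMP and TGF-beta, 0 for Hedgehog, 2 for FGF and 7 for Eph and ephrin genes.

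Markers that later distinguish layers of the dermis were already read in part. Papillary and reticular markers were detected at 11 of 15 (random lists 3 to 10), with the papillary markers Dpp4 (63.8 ± 4.83), Lrig1 (563.6 ± 18.6) and Col23a1 (242 ± 4.86), and markers of the reticular lineage were among the 11 as well. Ntn1 (-3.04 ± 8.16), the adipogenic regulator Pparg (13.5 ± 5.97) and Aspn (12.5 ± 7.79) were not detected. Dermal condensate and papilla markers were detected at 14 of 21, at the upper end of the random range of 5 to 14. They included Sox18 (277 ± 9.01), Foxd1 (63.2 ± 13.5) and Bmp4, and Sox2, a marker of the condensate, at 46.8 ± 7.49 by 1 of 2 probes. Sox18 is also a member of the endothelium list. Prdm1 (8.97 ± 10.2) and Fgf7 (34.7 ± 23.1) were not detected, Fgf7 passing on 2 arrays. Markers of fascia and adventitial fibroblasts were detected at 6 of 13, within the random range of 2 to 9. Among them were Gpx3 at 386 ± 32, Ly6a at 180 ± 3.75 and Cd34, which is also in the endothelium list, at 97.1 ± 12.9. Pi16 (-3.61 ± 8.31) and Cd55 (-0.402 ± 1.42) were not detected.

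Regulators of the somite and its compartments were detected at 10 of 22, within the random range of 5 to 14. The homeobox genes Meox1 (128 ± 16.3) and Meox2 (196 ± 9.22) and the basic helix-loop-helix gene Tcf15 (73.1 ± 9.43) were detected. None of the 9 Pax genes was, including the dermomyotome genes Pax3 (-3.06 ± 2.36) and Pax7 (-11.1 ± 6.03) and the sclerotome genes Pax1 (20.9 ± 11.6) and Pax9 (7.95 ± 4.89), against 1 to 7 in random lists. T-box genes were detected at 4 of 16 (random lists 3 to 11), namely Tbx1 (93.5 ± 5.92), Tbx2 (467 ± 43.3), Tbx3 (3394 ± 112) and Tbx18 (99.3 ± 19.3). Sox genes were detected at 9 of 16 (random lists 3 to 11), falling to 4 with every probe required, and Sox1 (-1.63 ± 12.3), Sox3 (-2.78 ± 3.43) and Sox4 (10.6 ± 9.41) were not detected. Fox genes were detected at 10 of 42, below the random range of 12 to 25, with Foxc1 at 151 ± 8.37 and Foxc2 at 203 ± 9.39.

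Hox genes, whose nested expression marks position along the body axis, were detected at 21 of 39, within the random range of 11 to 23. Paralog groups 1 to 9 contributed 19 of 27 and groups 10 to 13 contributed 2 of 12. By cluster, 5 of 11 Hoxa, 7 of 10 Hoxb, 3 of 9 Hoxc and 6 of 9 Hoxd genes were detected. Among them were Hoxb2 (1117 ± 153), Hoxa5 (752 ± 75), Hoxb4 (730 ± 57.3), Hoxc6 (4395 ± 200), Hoxa7 (540 ± 13.3), Hoxd8 (428 ± 14), Hoxb9 (612 ± 42.4) and Hoxc9 (845 ± 44.3). The 2 posterior genes detected were Hoxd10 at 162 ± 18.2 and Hoxa13 at 45.7 ± 21, the latter by 1 of 3 probes and with values of 34.5, 69.9 and 32.8. At a detection p of 0 on all 3 arrays the counts were 17 for groups 1 to 9 and 1 for groups 10 to 13. Hoxd11 (20.2 ± 16.7), Hoxd12 (10.9 ± 7.91), Hoxd13 (16.3 ± 23.3), Hoxc11 (-9.75 ± 12.4) and Hoxb13 (-10.9 ± 10.6) were not detected, nor were Hoxb1 (3.02 ± 7.82), Hoxa3 (2.69 ± 5.40), Hoxb8 (-2.84 ± 5.52) and Hoxc8 (10.5 ± 6.72) among the anterior and central groups.

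**Figure D3:**
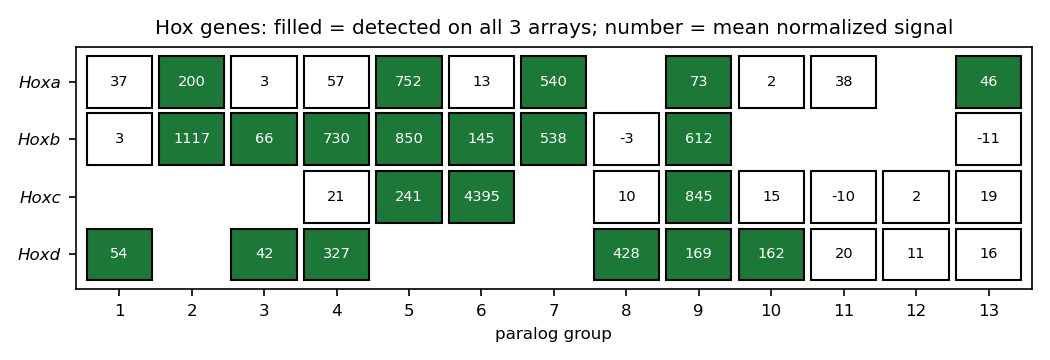
Grid of the 39 measured Hox genes, with paralog groups 1 to 13 along the horizontal axis and the 4 clusters as rows. Filled squares were detected on all 3 arrays and the number is the mean normalized signal in arbitrary units; 19 filled squares lie in groups 1 to 9 and 2 in groups 10 to 13.

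Markers of other cell types that embryonic skin or its surroundings could hold were also read above background. Over 11 such lists 121 of 237 genes were detected (51.1%), where random sets gave 88 to 119. Because the random sets also hold chemosensory genes, which are rarely detected, this small difference is not read as an excess. Of the 237 genes, 5 were also in a dermal or related list, namely Alpl, Cd34, Ebf2, Pparg and Sox18. Skeletal muscle was detected at 14 of 20 (random lists 4 to 13), with Myog (139 ± 21.4) and the sarcomere genes Actc1 (3236 ± 151) and Acta1 (874 ± 38), but without Myod1 (31.2 ± 21.4) or Myf5 (-6.01 ± 4.68). Endothelium was detected at 18 of 24 (random lists 6 to 15), with Pecam1 (220 ± 47.2), Cdh5 (82.3 ± 7.63), Tek (179 ± 14.3) and Flt1 (273 ± 10.1), but not Kdr (11.2 ± 2.51). Epidermis and periderm were detected at 21 of 34, at the top of the random range of 9 to 21, with the basal keratin genes Krt14 (1313 ± 58.6), Krt15 (287 ± 13.1) and Krt5 (72.2 ± 8.97). Over the whole keratin family 9 of 46 were detected, below the random range of 14 to 27, and Krt1 (-6.16 ± 5.50) was not. Macrophage, mast cell and other immune markers were detected at 17 of 27 (random lists 7 to 17), with Csf1r (164 ± 8.73), Aif1 (103 ± 26) and Adgre1 (387 ± 17.2), but not Ptprc (3.46 ± 5.57). That count was 11 with every probe required. Erythroid markers were detected at 14 of 23 (random lists 5 to 15), with the alpha-like globin genes Hba-a1 at 48801 ± 15629 and Hba-x, an embryonic form, at 3797 ± 167.

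Cartilage markers were detected at 10 of 19 (random lists 4 to 12), with Sox9 (456 ± 18.2), Col2a1 (2350 ± 101) and Col9a2 (849 ± 127). Bone markers gave 3 of 14 (random lists 3 to 10), namely the osteoblast factor Sp7 (1149 ± 20.1), Spp1 (39.2 ± 8.80) and Phex (73.1 ± 12.8), without Runx2 (1.98 ± 2.68), and 1 of 14 at a detection p under 0.001. Pericyte and smooth muscle markers gave 7 of 14 (random lists 3 to 10), with Acta2 at 14639 ± 2200 and Pdgfrb at 182 ± 15.8, but not Rgs5 (1.79 ± 25.8). Neuronal markers gave 11 of 29 (random lists 8 to 18), with Stmn2 (997 ± 26.7) and Nefm (263 ± 27) but not Tubb3 (12 ± 7.86), and 7 with every probe required. Neural crest, Schwann cell and melanoblast markers gave 3 of 16 (random lists 3 to 11), namely Fabp7 (125 ± 31.4), Ngfr (456 ± 18.8) and Ednrb (1586 ± 61.6). Adipocyte markers gave 4 of 18 (random lists 4 to 12), namely Cebpb (201 ± 8.99), Lpl (914 ± 67.9), Ebf2 (150 ± 23) and Dgat2 (196 ± 33.9).

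Genes of tissues far from the skin were mostly at background. Testis and retina genes gave 0 of 23 (random lists 5 to 15), with the protamine gene Prm1 at -5.81 ± 3.05, and 1 of 23 at a detection p under 0.05. Mesothelium, kidney and gut genes gave 2 of 18 (random lists 4 to 12), both of them mesothelial, Wt1 at 603 ± 39.8 and Upk3b at 540 ± 25.9. Hepatocyte and pancreas genes gave 7 of 27 (random lists 7 to 17), with the fetal plasma protein gene Afp at 262 ± 21, Apoa1 at 118 ± 11.5, Apoa2 at 123 ± 7.89 and Ttr at 242 ± 15.5, but without Alb (1.1 ± 3.74). Olfactory receptors gave 3 of 1079 (random lists 440 to 502), and vomeronasal receptors (0 of 143, random lists 51 to 74), taste receptors (0 of 35, 10 to 21), beta-defensins (0 of 40, 11 to 24) and the prolactin family (0 of 22, 5 to 14) gave none. The olfactory count was 8 at a detection p under 0.05, 1 at under 0.001 and 25 when detection on at least 1 array sufficed. Under 0.05, and likewise with 1 array, the vomeronasal count was 4 and the beta-defensin count 1, and the vomeronasal count was 1 without array 2 and with at least 2 arrays. Interleukin genes gave 3 of 36 (random lists 10 to 22), namely Il16 (150 ± 6.81), Il17d (112 ± 3.99) and Il33 (52.3 ± 11.6), kallikreins gave 1 of 23 (random lists 5 to 15; Klk8, 286 ± 34), and interferon genes gave 1 of 16 (random lists 3 to 11; Ifna6, 61.4 ± 10.8, by 1 of 2 probes). Interleukins were 5 at a detection p under 0.05 and with at least 1 array, kallikreins 2 with at least 1 array, and both kallikreins and interferon genes 0 with every probe required.

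Cell cycle genes were broadly detected. G1/S and DNA replication genes gave 22 of 28 (random lists 7 to 17), with the replication licensing genes Mcm2 (827 ± 10.6), Mcm4 (5408 ± 404) and Mcm5 (2293 ± 70.4), and 14 with every probe required. G2/M and mitosis genes gave 21 of 27 (random lists 7 to 17), with Cdk1 (474 ± 23), Ccnb1 (1058 ± 94.5) and Cdc20 (1590 ± 26.3). Hypoxia and glycolysis genes gave 16 of 22 (random lists 5 to 14), with Vegfa (1103 ± 73.8), Slc2a1 (1835 ± 152) and Ldha (5678 ± 367). Immediate early and heat shock genes gave 15 of 23, at the top of the random range of 5 to 15, with Egr1 (996 ± 21) and Jun (455 ± 29.4), while Fos (49.1 ± 8.92) and Junb (46.7 ± 4.45) were near background. Interferon response genes gave 6 of 24 (random lists 6 to 15), such as Irf1 (235 ± 17.9) and Ifit2 (68.9 ± 6.66) but not Isg15 (15.6 ± 13.1), with 3 at a detection p under 0.001 and 1 with every probe required. Reference genes gave 15 of 18 (random lists 4 to 12), among them Gapdh (15346 ± 1498) and Hprt (1084 ± 34.2), and 9 with every probe required. Among the reference genes not detected were Pgk1 (2.30 ± 6.35) and Polr2a (-9.98 ± 6.28). Ribosomal proteins of the cytosol (61 of 68, random lists 22 to 38) and of mitochondria (70 of 76, 25 to 42), proteasome subunits (30 of 36, 10 to 22) and NADH dehydrogenase subunits (32 of 34, 9 to 21) were largely detected, with Rpl4 at 1418 ± 16.9, Mrpl2 at 1034 ± 148, Psma4 at 4091 ± 260 and Ndufa1 at 4982 ± 60.8.

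Transcripts from both the X-linked and the Y-linked genes of the sex-linked list were read, 2 of 5 in all (random lists 0 to 4). Xist, transcribed from the inactive X chromosome of females, lay at 390 ± 27.4 and both of its probes were detected. Of 4 Y-linked genes, Ddx3y was detected at 2276 ± 834 by 1 of 3 probes, while Eif2s3y (6.11 ± 5.63), Kdm5d (44.9 ± 5.73) and Uty (27.3 ± 15.3) were not. Kdm5d passed the threshold on 2 arrays and Uty on 1. The count of sex-linked genes was 4 with at least 1 array and 1 with every probe required.

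Over the 9693 probes detected on all 3 arrays, the SD of log2 normalized signal had a median of 0.11 and a 95th percentile of 0.37. Across these probes, which are not independent replicates, Pearson's r was 0.996 between arrays 1 and 3, 0.989 between arrays 1 and 2, and 0.989 between arrays 2 and 3. The median absolute log2 difference was 0.09 for arrays 1 and 3, 0.15 for arrays 1 and 2 and 0.15 for arrays 2 and 3. Without array 2 the median SD was 0.067, against 0.105 without array 1 and 0.105 without array 3. Each of these is an SD over 2 arrays on the probes detected on both. They are therefore set against each other and not against the 0.11 of 3 arrays. Array 2 was the dimmest before normalization, with a median signal of 83.8 against 107 and 112, and its normalization slope was 3.07 times that of array 1. Its log2 excess over the mean of arrays 1 and 3 was 0.13 for probes of 150 to 200 on array 1 (1082 probes), -0.05 at 200 to 300, -0.01 at 500 to 2000, 0.14 at 5000 to 10000, 0.39 at 20000 to 40000 and 0.59 at 40000 to 70000 (25 probes, 1.5-fold). The value at 150 to 200 is partly set by the choice of probes detected on every array, since the lowest detected signal was 44.3 on array 2 against 23.1 and 31.2 on arrays 1 and 3. Array 3 minus array 1 reached -0.07 at most in size over the same ranges. Bright genes such as Hba-a1 (39600, 66847 and 39956 on arrays 1, 2 and 3) and Igf2 (40521, 62103 and 36043) carried this difference. The 10 genes with the largest SD of log2 signal were led by 1 of 5 Actb probes (378, 1640 and 367, SD 1.24) and by Ulk4 (632, 2295 and 649, SD 1.06). Chrnb1 was lower on array 2, at 140, 48.6 and 139.

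**Figure D4:**
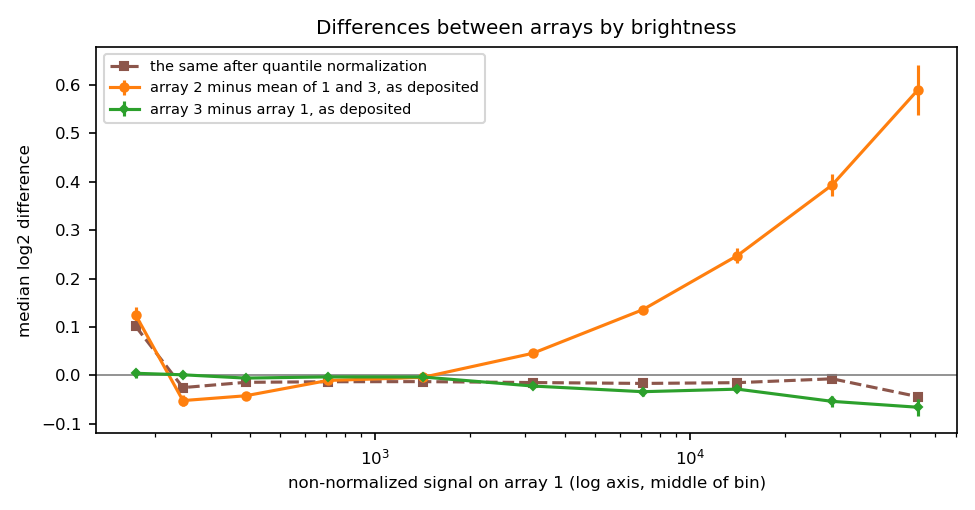
Median log2 difference in normalized signal between arrays, by non-normalized signal on array 1 (logarithmic axis, middle of each range, arbitrary units), for detected probes; bars are bootstrap standard errors. Array 2 lies 0.13 above the mean of arrays 1 and 3 at the dimmest probes and 0.59 above it at the brightest, array 3 minus array 1 reaches -0.07, and after quantile normalization array 2 differs by 0.10 at the dimmest and -0.04 at the brightest probes.

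Of the 17849 genes, 12813 were read by 1 probe and 5036 by several. All probes were detected in 910 of the latter, none in 2060, and some but not all in 2066, so the probes agreed in 59.0% of these genes. Of the genes named above, Lef1, Sox2, Col3a1, Wnt7b, Bmpr1a, Notch4, Efna5, Csf1r, Flt1, Myog, Ifit2, Ifna6, Il17d, Klk8, Rpl4 and Chrnb1 were detected by 1 of 2 probes, and Tcf7l2, Mcm4, Cdk1, Fgfr2, Smo, Ddx3y and Hoxa13 by 1 of 3. Adgre1, Aif1, Col6a1, Dusp6, Ednrb, Fgf10, Hprt, Sema3f, Tbx3 and Vegfa were detected by 2 of 3, Prrx1 and Cdc20 by 3 of 4 and Irf1 by 2 of 5. Like En1, the genes Lef1, Sox2, Foxd1, Dpp4, Tcf15, Wnt3a, Wnt11, Hoxa13, Etv5, Fos, Junb, Spp1, Phex, Il33 and Chrnb1 lost their call at a detection p under 0.001.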

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

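Chosen after seeing the data were a detection p of 0 on all 3 arrays, file symbols as given, quantile normalization of the normalized signal, and array 2 as the dim array to leave out, which was also 1 of the planned omissions; the other alternatives were chosen before. Of 27 main results, 19 stayed within their margins under every alternative run. All 27 are counts, percentages or SDs without a direction, so none could reverse. The margin for counts was a factor of 1.5, which the dermal lineage (23 of 28) and matrix (24 of 28) lists could not exceed upward. The series value table and the detection p of the normalized table equal the values used, so they could not move a result. Genes detected ranged from 5718 to 9232, the dermal lineage list from 18 to 26, the dermal matrix list from 20 to 24, the Wnt list from 17 to 23 and Hox genes from 18 to 25. Bone markers, 3 as reported, were 1 at a detection p under 0.001, 1 at a detection p of 0 and 5 when detection on at least 1 array sufficed. Neural crest, Schwann cell and melanoblast markers were then 5, against 3. With every probe of a gene required, immune markers were 11 against 17 and neuronal markers 7 against 11, as a stricter rule can only lower a count. Testis and retina genes were 1 at a detection p under 0.05 against 0. The median SD of log2 signal, 0.109 as reported, was 0.725 with no normalization between arrays and 0.0759 after quantile normalization, and its 95th percentile was 0.910 and 0.192 in place of 0.368. With all probes included and signals under the floor set to it, the median SD was 0.0170. Leaving out 1 array at a time gave a median SD of 0.0674 to 0.105, the lowest without array 2, and 7798 to 8388 genes detected. Those SDs were over 2 arrays and other sets of probes, so they are not comparable with the 0.109 of 3 arrays. Probes of a gene agreed in 57.5% of genes at a detection p under 0.05 and in 60.6% at under 0.001, against 59.0%, and the cause was not tested. Of 479 named genes, 447 kept their detection state at under 0.001, 457 at under 0.05, 429 with every probe required and 460 without array 2, where 19 calls were gained. After quantile normalization of the normalized signal, the mean of 477 of them stayed within 1 SD. Random lists matched on probes per gene moved 10 of 60 list percentiles, such as hepatocyte and pancreas (from 3.01 to 6.47) and cartilage (from 77.9 to 66.6). With them, 2 lists crossed an edge of the central range, the interferon response from percentile 3.16 to 1.73 and immune markers from 97.745 to 97.49. The signal over background limits calls near the threshold, such as those of En1, Sox2 and Lef1. No paired analysis was possible because the series held 1 group.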

Other observations

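The lists of imprinted, retinoic acid pathway and abundant cell type transcripts were written after other values had been seen, for the cell types those of the same genes, as were the tests of a bending response, of a scanner ceiling, of signal without transcript and of each candidate cell type. Their bounds were set then too. The tests of another RNA on array 2, of different transcripts and of signal near the threshold were set with the patterns known but before their own values were seen. Sst, Ins2, Gcg, Hbb-y, Hbb-bh1, Myl4 and C1qb were also chosen here after their values were seen. Imprinted genes, many of which control growth of the embryo, were detected at 18 of 27, where random lists gave 7 to 17, and 2 of the 27 (Dcn and Dlk1) were also in dermal lists. Because random lists also hold chemosensory genes, which are rarely detected, this small difference is not read as an excess. The growth-restraining genes H19 (15067 ± 2253), Cdkn1c (32311 ± 7741) and Grb10 (9523 ± 1133) were detected, as were Mest (4968 ± 358), Ndn (9086 ± 1099) and Peg3 (309 ± 6.76) (SD, n = 3 arrays). Plagl1 (-2.42 ± 4.2), Rtl1 (-5.44 ± 7.84) and Ascl2 (0.011 ± 4.43) were not.

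Genes of the retinoic acid pathway were detected at 10 of 19, within the random range of 4 to 12. The binding protein gene Crabp2 (682 ± 63), the receptor gene Rarb (291 ± 49.3) and the synthesis genes Aldh1a1 (284 ± 14.7), Aldh1a2 (69.3 ± 15.8) and Aldh1a3 (343 ± 20.9) were detected, Aldh1a2 by 1 of its 2 probes and Rarb by 2 of 3. The degrading enzyme genes Cyp26a1 (-3.5 ± 6.92) and Cyp26b1 (13 ± 5.04) were not. Sst, which encodes the peptide hormone somatostatin, lay at 6970 ± 555 with its 1 probe, although the pancreas genes Ins2 (5.99 ± 8.47) and Gcg (-12.7 ± 2.5) were not detected. The embryonic beta-like globin genes Hbb-y (47177 ± 15485) and Hbb-bh1 (5750 ± 266) were detected beside the adult forms Hbb-b1 (1824 ± 269) and Hbb-b2 (2265 ± 365).

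Bright probes read higher on array 2 than on arrays 1 and 3 in the deposited normalized table. A hard ceiling of the scanner alone would leave probes far below the highest signal unmoved, but the log2 difference had already risen by 0.14 (bootstrap SE 0.01, 311 probes) at 5000 to 10000. A response that bends with brightness and is kept by 1 slope and 1 offset per array stays open, because the rise of 0.47 (SE 0.03) from probes of 500 to 2000 to probes above 20000, against 0.05 for array 3 minus array 1, is the pattern itself. Another RNA on array 2 could not be excluded, since, with the trend by brightness removed, the variance of array 2 minus array 1 was 1.39 times (95% interval 1.30 to 1.49, 6970 probes) that predicted from arrays 1 and 3, between the bounds set for it. No biological explanation was tested, because the labels give 1 RNA pool for all 3 arrays.

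Markers of other cell types lay above background in RNA meant to come from dermal progenitors. For probes that give signal without their transcript, the rate in chemosensory and beta-defensin genes predicts 0.548 genes. With 121 detected the ratio was 221, above the bound, which was set after other values had been seen. The rate in lists of unrelated tissues, 9 of 68, predicts 31.4, a ratio of 3.86, which lay below that bound. Whether those 9 signals lack their transcripts was not tested. They include the mesothelial genes Wt1 and Upk3b, so this rate may count true transcripts. At neither rate would such signal alone give 121 genes, but a part of them from it was not excluded. Lists of abundant transcripts were detected at 7 of 7 for red cells (Hba-a1 at 48801 ± 15629), 8 of 8 for muscle (Myl4 at 7575 ± 753), 7 of 8 for macrophages (C1qb at 213 ± 26.1), 7 of 8 for epidermal cells (Krt14 at 1313 ± 58.6) and 4 of 8 for neurons (Stmn2 at 997 ± 26.7). All of these genes were already among the markers counted above, so the lists restate the pattern, and RNA from each of these cell types stays open. Transcription of these genes in the progenitors themselves also stays open and no biological explanation was tested, as microdissection was the selection applied and 0 RNAs in this 1 pool could separate cell types.

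Probes of the same gene often differed in detection, with some but not all detected in 2066 of 5036 genes. In 11.8% of 3948 disagreeing pairs (95% interval 10.4 to 13.05) the undetected probe had a detection p under 0.05 on all arrays. This argues against undetected probes that lie near the threshold on every array as the main cause. A probe that missed 0.05 on only 1 array was not counted as near, and how close the detected probe lay was not tested. Signal close to the threshold on some arrays therefore stays open. For probes that read different transcripts of a gene, pairs with different transcript keys disagreed in 36.7% and pairs with the same key in 32.7%. Their ratio was 1.12 (bootstrap SE 0.0441, 95% interval 1.04 to 1.21). It lay under the 1.2 set as the bound against this cause, but its interval reached past 1.2, so the test cannot decide. The interval stayed below the higher ratio that had been set as the sign of this cause. The cause stays open, probe sequences and positions were not analysed here, and no biological explanation was tested.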
